A study of Homo sapiens with 15 samples.

How the data were processed

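Stranded mRNA libraries (KAPA mRNA HyperPrep kit on RNA from a Direct-zol kit, per the labels' protocols) were sequenced from 5 stable MCF10A lines, with 3 biological replicates per line and 15 libraries in all. The deposited files give 1 raw read count per gene and library for 26486 genes. Per the submitters' processing notes, the authors counted reads with featureCounts 1.6.4 on hg38; the aligner, the annotation and the strand setting are not given in the sources used here. A row named mMYC, for the mouse MYC transgene, follows the human genes in each file. How reads that match both human MYC and mMYC were assigned is not stated either, so those 2 genes may share reads. No symbol starts with MT-, so the list of mitochondrially encoded genes had 0 members. Coordinates were taken from GENCODE 29 on GRCh38, in which 23825 symbols matched 1 gene.

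Total counts ranged from 11688046 to 21413590 per library (median 15864752). A gene with 0 counts in all libraries of a group was treated as lying below a floor of 3 counts per library, and its change is given as a lower bound. For a gene with 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only. Levels are CPM, counts relative to the library total, after scaling by the trimmed mean of M values (TMM), as mean ± SD of 3 libraries.

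The groups, comparisons, tests, gene lists and first set of alternatives were chosen before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM factors, filterByExpr by group), with all 15 libraries in 1 model that had a term per group. After this filter 13622 genes passed, which is 51.4% of the listed genes and held 99.95% of the counts. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison; all gene p-values below are of this kind. The comparisons, 10 in number, were WT against EV, each mutant against WT, each mutant against EV, and each pair of mutants. An F-test for any difference among the 5 groups was added to them in the same design. The biological coefficient of variation was 0.0367.

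In all, 39 gene lists with 968 distinct members were written from general knowledge; 951 members matched a symbol in the files, 57 of them through an older symbol or synonym. Lists with at least 4 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison. Each list was tested again with a correlation estimated from the residuals and with fry. The members of a list were also counted with p adjusted over the list alone. Some genes were in several lists, so the calls of lists that share members are not independent.

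Genes were named by a fixed rule. A named gene had to be called, to have a mean of at least 2 CPM in a group and to have complete separation of the libraries (a pattern chance gives to 10% of unchanged genes with 3 against 3). Among such genes the 6 highest and 6 lowest fold changes were named for WT against EV and each mutant against WT, and 3 and 3 for the other comparisons. For R158 against WT, 1 gene that the rule names is not reported here. Of each list discussed, up to 4 called members with the smallest p were named, and a member named as not called was the most abundant one. MYC was read in every library. For genes that moved in the same direction in all 3 mutants, the 6 with the smallest p per direction were named, and for genes of the WT response that moved back towards EV, 4 per mutant. Genes that share reads with near-identical copies (KRT6A, KRT6B and KRT6C, RN7SL1 and RN7SL2, SPRR genes, HSPA1A, HLA genes, KIR genes, histones and zinc finger genes) have uncertain levels.

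Alternatives fixed beforehand were size factors of the RLE type, library totals alone, limma-voom, DESeq2 1.42.0, no filter beyond 1 count in total, a filter of 10 CPM in 3 libraries, the replicate number as a block, the 2 groups compared alone, and each replicate left out in turn. A pair of alternatives was added after the data had been seen: without 3 libraries that stood apart from their groups (WT replicate 1, EV replicate 2 and R158 replicate 1), and with WT replicate 1 as the only WT library, which takes its spread from the other groups. DESeq2 gave no adjusted p for 3925 to 6671 of the genes per comparison, because of its own filter on low counts. The fewest were in WT, R158 and R323 against EV and in R158 against R149, and the most in R323 against R149.

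The WT response carried by a mutant was counted over the genes called in WT against EV. Since all comparisons share their controls, 100 sets of counts were simulated with unchanged groups and 100 with mutants equal to WT. The 3 control libraries cannot be split with 2 on each side. The fits were tested on simulated data: of 98 genes changed by a fold of 2 in simulated WT against EV libraries (13225 genes tested), 92.9% were called, and of 98 changed by a fold of 1.25, 67.3% were called. There 9 of 13029 unchanged genes were called. Chromosomal regions were read from the medians of genes with at least 2 CPM, in bins of 20 Mb with at least 20 genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.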

Results

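Messenger RNA was sequenced from 5 stable lines of MCF10A, a non-transformed human mammary epithelial cell line. Each line carried an empty vector (EV), mouse MYC of wild-type sequence (WT), or mouse MYC in which a lysine was replaced by arginine: K149R (R149), K158R (R158) or K323R (R323). Arginine keeps the positive charge of lysine but cannot be acetylated. Each mutant thus addresses an acetylation site of MYC, a transcription factor that drives cell growth, in transformation and in the choice of target genes. Acetylation, MYC protein and transformation were not measured in these mRNA libraries, so a difference need not come from lost acetylation. Each line gave 3 biological replicates, 15 libraries in all. The libraries held 14812861 to 21413590 counts in EV, 18214386 to 18989170 in WT, 14664545 to 18776169 in R149, 14956523 to 19559690 in R158 and 11688046 to 15864752 in R323. Between 16186 and 16810 genes had at least 1 count per library. The 10 most abundant genes took at most 3.926% of a library's counts. There was 1 stable line per construct, so the construct and the line that carries it cannot be told apart, and all p-values measure the spread between replicates of a line. The libraries of each group lay together on the first principal components. The first (35.9% of the variance) ordered EV, R158, WT, R323 and R149, and the second (33.5%) set WT and R158 on one side and EV, R149 and R323 on the other. Some difference among the 5 groups was called for 11711 of 13622 genes (86%, edgeR F-test).

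The transgene was read in every library first, since it checks the labels. The mouse MYC row, mMYC, had 0 counts in each EV library, which allows at most 0.14 to 0.203 CPM. In WT it had 11759, 12287 and 12267 counts, or 653 ± 4.33 CPM. It reached 469 ± 24.5 CPM in R149, 425 ± 13.4 CPM in R158 and 580 ± 20.6 CPM in R323. Those levels were at least 3.22e+03-fold higher than EV in WT, and at least 2.31e+03-fold, 2.09e+03-fold and 2.86e+03-fold higher in R149, R158 and R323. Every mutant had less mMYC mRNA than WT, with log2 changes of -0.48 in R149 (edgeR adjusted p = 3.53e-11), -0.62 in R158 (adjusted p = 4.83e-13) and -0.17 in R323 (adjusted p = 0.000375). The human MYC gene, the cell's own copy, fell where the transgene was present. It stood at 358 ± 8.39 CPM in EV, 134 ± 4.96 in WT, 188 ± 5.71 in R149, 211 ± 5.38 in R158 and 187 ± 8.74 in R323. Against EV the log2 change of human MYC was -1.42 ± 0.039 in WT (adjusted p = 7.86e-22), -0.93 in R149, -0.77 in R158 and -0.94 in R323. Against WT it rose by 0.49 in R149, 0.65 in R158 (adjusted p = 1.31e-13) and 0.48 in R323 (adjusted p = 1.11e-10). How reads that match both MYC rows were divided is not known, so the 2 levels may be mixed to some degree. The counts of mMYC exceeded those of human MYC 4.65 to 5.054 times in WT, 2.346 to 2.597 times in R149, 1.918 to 2.104 times in R158 and 2.849 to 3.344 times in R323.

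**Figure D1:**
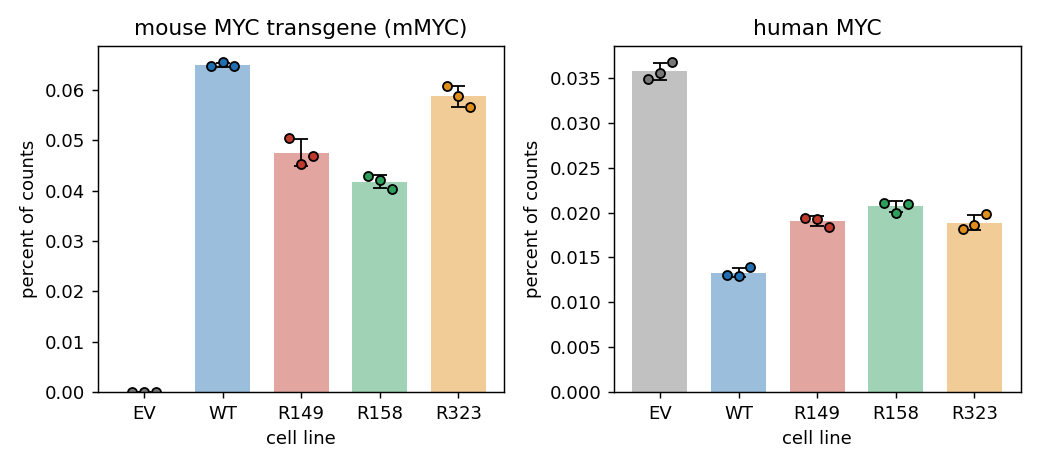
Percent of each library's counts in the mMYC row (left) and the human MYC row (right) for the 5 lines, with bars for the mean ± SD and points for the 3 libraries. WT libraries had 0.0646 to 0.0654% of counts in mMYC and EV libraries 0, while human MYC took 0.0349 to 0.0367% in EV and 0.0129 to 0.0139% in WT.

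WT was compared with EV to ask what added MYC changed in these cells. Genes of ribosome assembly rose and genes of the extracellular matrix fell. Genes of keratinocyte differentiation, the programme of the outer layers of skin, rose more than any other list. Lists of mitochondrial ribosomes, respiration, chaperones and DNA replication also rose, but these calls were lost with an estimated correlation (adjusted p = 0.0626, 0.133, 0.118 and 0.497). The same held for the falls of cell adhesion genes and of the amino acid stress response (adjusted p = 0.0626 and 0.178 with an estimated correlation). Of 13622 genes tested, 8215 were called, 4176 higher and 4039 lower in WT; 438 rose and 708 fell by at least 2-fold. With the WT library that shares a high 7SL RNA level with EV (WT replicate 1) as the only WT library, 6688 were called; this lone library was assumed to vary like the other groups.

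The nucleolar list, the factors that make and assemble ribosomes, rose in WT in 47 of 47 members (median log2 change 0.48, camera adjusted p = 5.62e-20). Counts adjusted over the list alone were the same here and for each list of WT against EV, except where a second count is given. Nucleolin (NCL), which binds ribosomal RNA precursors, rose from 1315 ± 48.4 to 1998 ± 100 CPM, and NPM1, a nucleolar chaperone, from 1310 ± 12.5 to 1940 ± 85.8 CPM. Among mitochondrial ribosomal proteins and import factors 33 of 33 rose (median 0.46, adjusted p = 2.61e-12), and among nuclear-encoded genes of oxidative phosphorylation 28 rose and 3 did not (median 0.27, adjusted p = 7.11e-07). With an estimated correlation the adjusted p = 0.0626 and 0.133. C1QBP, a mitochondrial matrix protein, rose from 330 ± 7.98 to 489 ± 4.47 CPM, and cytochrome c (CYCS), an electron carrier, from 357 ± 12.2 to 521 ± 26.7 CPM. Of the chaperones, which fold other proteins, 23 of 24 rose (median 0.49, adjusted p = 2.81e-14; adjusted p = 0.118 with an estimated correlation). HSPD1, the mitochondrial folding chamber, rose from 1241 ± 24.2 to 2015 ± 107 CPM. Cytosolic ribosomal proteins rose by less, in 37 of 38 members (median 0.25, adjusted p = 7.08e-08; adjusted p = 0.307 with an estimated correlation). RPL37, of the large subunit, had a log2 change of 0.50 ± 0.031. It starts at 40825262 on the short arm of chromosome 5, outside the bins below 40 Mb that were raised in WT. In nucleotide synthesis 23 of 25 rose and 1 fell (median 0.34, adjusted p = 9.02e-07; adjusted p = 0.156 with an estimated correlation), UMPS, which makes UMP, by 0.69 ± 0.051. RRM1, a subunit of ribonucleotide reductase, was not called (adjusted p = 0.293).

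In WT against EV, for entry into S phase and DNA replication 30 of 36 rose and 1 fell, or 31 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 0.00019; adjusted p = 0.497 with an estimated correlation). CDC25A, a phosphatase that starts S phase, rose from 34.3 ± 3.07 to 63.6 ± 2.06 CPM, whereas cyclin D2 (CCND2), which opens the cycle, fell by 0.49 ± 0.037. Of the genes of G2 and mitosis 15 rose, 2 fell and 13 were not called (median 0.10, adjusted p = 0.133). CDC20, which starts anaphase, rose by 0.53 ± 0.055. The list of CDK inhibitors and growth arrest genes had 6 up and 8 down (median -0.10, adjusted p = 0.787). Targets of p53 had 13 up and 11 down; their median was 0.12 while the test pointed down (adjusted p = 0.97). Among apoptosis regulators 6 rose and 12 fell (median -0.13, adjusted p = 0.401). MCL1, which keeps cells alive, fell from 2747 ± 118 to 1933 ± 57 CPM.

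The targets of ATF4, which answers a shortage of amino acids, fell in WT against EV in 18 of 20 members with 1 up (median -1.20, adjusted p = 1.01e-10; adjusted p = 0.178 with an estimated correlation). CHAC1, which degrades glutathione, fell from 37 ± 8.24 to 2.45 ± 0.857 CPM, and SLC7A11, a cystine importer, from 174 ± 36.8 to 57.3 ± 2.5 CPM. EV replicate 2 stood apart in this list (mean log2(CPM + 1) of 6.229, against 5.805 and 5.827 in the other EV libraries), and without it the median log2 fold change of list amino acid response (ATF4 targets), WT against EV, was -0.862. Fatty acid synthesis fell in 10 of 15 members, with 1 up (median -0.36, adjusted p = 9.64e-07), led by the desaturase FADS2 (138 ± 1.78 to 30.2 ± 1.26 CPM). The remaining metabolic lists were not called. Glycolysis had 14 up and 4 down (median 0.13, adjusted p = 0.0829), with HK2, which traps glucose, up by 0.95 ± 0.039. Serine and one-carbon metabolism had 3 up and 9 down (median -0.25, adjusted p = 0.193). Polyamine genes had 3 up and 3 down, 3 and 4 adjusted over the list alone, with a median of -0.06 and an upward test (adjusted p = 0.547); ODC1, its first enzyme, rose by 0.83 ± 0.034. Cholesterol synthesis had 4 up and 13 down, 4 and 14 adjusted over the list alone (median -0.11, adjusted p = 0.14). Translation factors and tRNA synthetases had 15 up and 8 down (median 0.14, adjusted p = 0.166), hypoxia genes 8 and 11 (-0.06, adjusted p = 0.419), targets of the antioxidant factor NRF2 14 and 4 (0.18, adjusted p = 0.0724) and lysosome genes 6 and 15 (-0.10, adjusted p = 0.124).

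In WT against EV, among matrix genes 23 of 33 fell and 6 rose (median -0.59, adjusted p = 4.3e-21). SPARC, a collagen-binding protein, fell from 48 ± 2.3 to 0.485 ± 0.0428 CPM (97.5-fold), and fibronectin (FN1), a major matrix protein, by 2.84 ± 0.049 on the log2 scale. Integrins and adhesion genes fell in 28 of 43 members and 12 rose (median -0.37, adjusted p = 3.71e-08; adjusted p = 0.0626 with an estimated correlation). ITGB6, an integrin of epithelial repair, fell from 216 ± 11.3 to 72.1 ± 3.29 CPM. Mesenchymal markers fell in 12 of 20 with 4 up (median -0.43, adjusted p = 9.82e-11), vimentin (VIM), a filament protein, by 0.84 ± 0.031. The mesenchymal list shares FN1 and SPARC with the matrix list. Keratinocyte differentiation genes rose in 23 of 29 and fell in 3 (median 2.17, adjusted p = 1.72e-44). PI3, a secreted protease inhibitor of skin, rose from 20.2 ± 1.65 to 428 ± 18.9 CPM (adjusted p = 2.02e-28), and S100A8, an alarm protein of stressed epithelium, from 21.4 ± 1.94 to 200 ± 6.51 CPM. Basal markers had 8 up and 11 down; their median was -0.23, their mean 0.25 and the test upward (adjusted p = 0.0502). The stress keratins KRT16 and KRT17 rose by 2.87 ± 0.069 and 2.19 ± 0.063, and KRT6B, which shares reads with its copies, by 3.47 ± 0.079. Luminal markers had 4 up and 4 down (median -0.06, adjusted p = 0.97).

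Targets of YAP and TEAD, which respond to cell spreading, fell in WT against EV in 17 of 21 with 1 up (median -0.61, adjusted p = 1.99e-09), CTGF, a matrix signal, from 26.2 ± 2.27 to 5.47 ± 0.765 CPM. Immediate early and MAPK feedback genes fell in 19 of 28 with 4 up (median -0.45, adjusted p = 9.33e-10; adjusted p = 0.05 with an estimated correlation, which is not below the threshold). DUSP6, which shuts off ERK, fell from 243 ± 15.4 to 104 ± 4.49 CPM. Inflammatory genes of NF-kB fell in 15 of 24 and 4 rose (median -0.44, adjusted p = 0.0156; adjusted p = 0.538 with an estimated correlation); the cytokine IL1B fell by 1.67 ± 0.074 and the acute-phase protein SAA1 rose by 1.69 ± 0.06. Interferon-stimulated genes had 7 up and 14 down (median -0.15, adjusted p = 0.272), antigen presentation 6 and 8 (-0.09, adjusted p = 0.422), TGF-beta targets 7 and 9 (median -0.05, mean 0.08, downward test adjusted p = 0.124) and the MYC network of partners and antagonists 14 and 5 (0.12, adjusted p = 0.36). Histone genes, which this mRNA protocol captures poorly, had 2 up and 1 down, 1 and 0 adjusted over the list alone (0.25, adjusted p = 0.636). Fibroblast markers had 3 up and 1 down (0.42, adjusted p = 0.787) and endothelial markers 0 and 3 (-0.76, adjusted p = 0.166). Leukocyte markers fell in 5 of 5 (median -1.33, adjusted p = 0.00161; adjusted p = 0.0848 with an estimated correlation). CD14, a receptor of monocytes, fell from 21.1 ± 4.14 to 8.52 ± 0.326 CPM and CD68, a macrophage lysosome protein, from 40.1 ± 2.35 to 28.8 ± 2.06 CPM.

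Some genes were switched on or off between the EV and WT lines. AUTS2, a chromatin cofactor (chromosome 7, 69598296 to 70793495), was at least 43.5-fold higher and PABPC4L, a poly(A)-binding protein (chromosome 4, 134196333 to 134201748), at least 15-fold higher in WT, both with 0 counts in EV. LOC389705, an uncharacterised locus, was at least 44.5-fold higher. ADD2, a membrane skeleton protein, rose 161-fold (log2 7.33 ± 0.225), and SLC16A14, a transporter, had a ratio of 190 (95% counting interval 52.2 to 1.57e+03). TUB, a signalling adaptor (chromosome 11, 8019244 to 8106112), was at least 76.7-fold lower, and ZNF354C, a zinc finger protein, at least 26.7-fold lower. MAP1B, a microtubule protein, fell by 6.37 ± 0.367, and the protease ADAMTS12 was lower by a ratio of 93 (31.5 to 454). ZNF737 was at least 13.7-fold lower, but with DESeq2 it was not called (adjusted p = 0.173), and it may share reads with related zinc fingers.

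R149 against WT addressed the K149R change. Replication and mitosis genes fell in R149, nearly without exception. Ribosome-making factors fell with them, and so did the keratinocyte programme, which had been higher in WT than in EV. Chaperones also fell and the amino acid stress response and ribosomal proteins rose, but these calls were lost with an estimated correlation (adjusted p = 0.0875, 0.0875 and 0.312). Of 13622 genes 8449 were called, 4254 higher and 4195 lower, 643 and 451 of them by at least 2-fold; without WT replicate 1, whose 7SL level is unlike that of R149, 8079 genes were called.

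Of the genes for S phase entry and replication 35 of 36 fell in R149 against WT (median -1.19, camera adjusted p = 3.29e-43), and of those for G2 and mitosis 29 of 30, with 1 up (median -0.79, adjusted p = 3.4e-31). For R149 against WT the counts adjusted over the list alone were the same except where a second count is given. CDC25A fell from 63.6 ± 2.06 to 19.9 ± 2.72 CPM (adjusted p = 4.39e-17), MCM4, part of the replicative helicase, from 250 ± 2.68 to 95.2 ± 10.5 CPM, and CLSPN, a checkpoint adaptor at replication forks, by 2.17 ± 0.094. CCND2 was not called (adjusted p = 0.624). MYBL2, a transcription factor of dividing cells, fell from 99.4 ± 2.99 to 34.3 ± 3.66 CPM. Growth arrest genes rose in 13 of 20 with 2 down (median 0.24, adjusted p = 0.000364; adjusted p = 0.0526 with an estimated correlation), CDKN1C, a CDK inhibitor, from 32.6 ± 2.61 to 86.3 ± 6.08 CPM. Targets of p53 rose in 18 of 25 with 2 down (median 0.29, adjusted p = 2.23e-05), GDF15, a stress hormone, from 14.2 ± 2.33 to 53.9 ± 4.24 CPM. Nucleotide synthesis fell in 23 of 25 with 1 up, 24 and 1 adjusted over the list alone (median -0.43, adjusted p = 8.74e-14); RRM2, which makes DNA precursors, fell from 232 ± 4.58 to 71 ± 8.3 CPM.

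Nucleolar factors fell in 44 of 47 in R149 (median -0.35, adjusted p = 1.87e-16), LYAR, a growth regulator of the nucleolus, from 160 ± 1.43 to 85.1 ± 5.78 CPM. Chaperones fell in 23 of 24 (median -0.49, adjusted p = 1.23e-16; adjusted p = 0.0875 with an estimated correlation); HSP90AA1, a folding chaperone of signalling proteins, fell from 3902 ± 152 to 1787 ± 197 CPM. Mitochondrial ribosomal genes fell in 26 of 33 with 4 up (median -0.30, adjusted p = 3.52e-05; adjusted p = 0.185 with an estimated correlation), and polyamine genes in 6 of 9 with 2 up (median -0.24, adjusted p = 0.00697; adjusted p = 0.106 with an estimated correlation). Ribosomal proteins rose in 37 of 38 with 1 down (median 0.18, adjusted p = 3.9e-06), and oxidative phosphorylation in 23 of 31 with 2 down, 24 and 2 adjusted over the list alone (median 0.14, adjusted p = 0.00697); with an estimated correlation the adjusted p = 0.312 and 0.364. ATF4 targets rose in 19 of 20 with 1 down (median 1.18, adjusted p = 4.73e-16; adjusted p = 0.0875 with an estimated correlation). ASNS, which makes asparagine, rose from 87.9 ± 5.35 to 352 ± 35.7 CPM, and PHGDH, which opens serine synthesis, from 49.6 ± 5.35 to 214 ± 22.3 CPM. Serine and one-carbon genes rose in 11 of 14 with 3 down (median 0.77, adjusted p = 0.000105; adjusted p = 0.142 with an estimated correlation). Cholesterol synthesis fell in 19 of 24 with 3 up, 20 and 3 adjusted over the list alone (median -0.28, adjusted p = 0.000103; adjusted p = 0.239 with an estimated correlation), HMGCS1, an early enzyme, by 1.24 ± 0.085.

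Keratinocyte genes fell in 28 of 29 in R149 against WT (median -1.98, adjusted p = 3.29e-43), PI3 from 428 ± 18.9 to 50.6 ± 4.33 CPM and SBSN, a secreted epidermal protein, from 62.6 ± 2.54 to 5.81 ± 0.516 CPM. Basal markers fell in 13 of 20 with 5 up (median -0.31, adjusted p = 2.69e-06), KRT16 by 1.90 ± 0.064. Matrix genes rose in 21 of 33 with 7 down (median 0.36, adjusted p = 0.000566; adjusted p = 0.201 with an estimated correlation), LAMB1, a laminin chain, from 384 ± 16.4 to 940 ± 77.1 CPM. NF-kB genes rose in 16 of 24 with 3 down (median 0.48, adjusted p = 0.00166; adjusted p = 0.414 with an estimated correlation), NFKBIA, the pathway's inhibitor, by 0.65 ± 0.039. Antigen presentation rose in 11 of 16 with 2 down (median 0.36, adjusted p = 0.00436; adjusted p = 0.142 with an estimated correlation). Fatty acid synthesis rose in 10 of 15 with 4 down (median 0.15, adjusted p = 0.00116). NRF2 targets rose in 11 of 23 with 4 down (median 0.20, adjusted p = 0.000667) and lysosome genes in 16 of 30 with 5 down (median 0.12, adjusted p = 0.0146); with an estimated correlation the adjusted p = 0.11 and 0.185. The largest rises were of FLRT1, an adhesion receptor (5.61 ± 0.523), PAPPA2, a protease of growth factor carriers (5.46 ± 0.433), TNFRSF9, a costimulatory receptor (5.16 ± 0.459), STAT5A, a cytokine signal carrier (4.51 ± 0.462), INHBE, an activin subunit (4.37 ± 0.313), and ADM2, a peptide hormone (4.11 ± 0.256). The largest falls were of LOC389705, by a ratio of 446 (79.7 to 1.77e+04), WFDC5, an antiprotease (at least 10.5-fold), and KRT6C, whose reads are shared with KRT6A and KRT6B (4.79 ± 0.139). LOC389705 was also lower in EV than in WT. LY6G6C, a surface protein, fell by 4.56 ± 0.424, DSG1, a desmosomal cadherin of skin, by 3.78 ± 0.217 and the keratin KRT78 by 3.74 ± 0.334.

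R158 against WT addressed the K158R change. R158 was the mutant closest to WT by number of calls: replication, mitosis and the amino acid stress response were not called as lists. Keratinocyte genes and antigen presentation fell in part, and matrix, YAP and MAPK feedback genes rose in part. None of these list calls held with an estimated correlation (adjusted p = 0.0871 and 0.131 for the falls and 0.155, 0.131 and 0.155 for the rises). Genes along the long arm of chromosome 19, from 27 Mb onwards, rose together. Of 13622 genes 4194 were called, 2087 higher and 2107 lower, 309 and 211 by at least 2-fold; without WT replicate 1, whose 7SL level is unlike that of R158, 3752 genes were called. Of the 4194 calls, 393 lay on chromosome 19 from 27 Mb onwards, 380 of them higher, which left 3801 elsewhere.

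None of the 18 lists called in R158 against WT held with an estimated correlation, so each is followed by that value. For replication genes 4 rose and 1 fell of 36, 4 and 0 adjusted over the list alone (median 0.03, camera adjusted p = 0.472), and POLD1, the catalytic subunit of a replicative polymerase, which lies on the long arm of chromosome 19, rose by 0.61 ± 0.049. MCM4 was not called (adjusted p = 0.759). In G2 and mitosis 12 of 30 rose and 1 fell, 13 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.102). ATF4 targets had 6 up and 1 down (median 0.08, adjusted p = 0.202). Of ribosomal proteins 7 rose and 13 fell, 7 and 15 adjusted over the list alone; the median was -0.05, the mean 0.04 and the test upward (adjusted p = 0.241). All 7 that rose lie on that arm, led by RPL28 (542 ± 27.8 to 1220 ± 45.4 CPM). Nucleolar factors fell in 16 of 47 with 3 up, 19 and 3 adjusted over the list alone (median -0.10, adjusted p = 0.00544; adjusted p = 0.43 with an estimated correlation), NPM1 by 0.23 ± 0.031. Mitochondrial ribosomal genes fell in 12 of 33 with 1 up, 16 and 1 adjusted over the list alone (median -0.11, adjusted p = 0.00529; adjusted p = 0.43 with an estimated correlation). Nucleotide synthesis enzymes fell in 9 of 25 with 1 up, 10 and 2 adjusted over the list alone (median -0.08, adjusted p = 0.0306; adjusted p = 0.544 with an estimated correlation), and the median log2 fold change of list nucleotide synthesis enzymes, R158 against WT, was not called without WT replicate 1 (adjusted p = 0.0789).

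Keratinocyte genes fell in 18 of 29 in R158 against WT with 4 up, 18 and 5 adjusted over the list alone (median -0.38, adjusted p = 1.31e-08; adjusted p = 0.0871 with an estimated correlation). Of the 29 genes, 6 lie on the raised long arm of chromosome 19. Among the 23 elsewhere 16 fell and 3 rose (median -0.526). PI3 fell from 428 ± 18.9 to 135 ± 1.4 CPM, while KRT4, a keratin of moist epithelia, rose by 1.42 ± 0.109. Basal markers had 9 up and 8 down, 10 and 8 adjusted over the list alone; the median was 0.05 but the mean -0.23 and the test downward (adjusted p = 0.000523; adjusted p = 0.145 with an estimated correlation). KRT14, a keratin of basal cells, fell from 239 ± 17.1 to 62.4 ± 5.6 CPM. Luminal markers fell in 6 of 14 with 1 up, 6 and 2 adjusted over the list alone (median -0.23, adjusted p = 0.00125; adjusted p = 0.0681 with an estimated correlation). Antigen presentation fell in 12 of 16, 12 and 1 up adjusted over the list alone (median -0.29, adjusted p = 0.000523; adjusted p = 0.131 with an estimated correlation), HLA-B from 101 ± 2.85 to 60 ± 0.96 CPM. NRF2 targets fell in 12 of 23 with 2 up (median -0.19, adjusted p = 0.000431; adjusted p = 0.131 with an estimated correlation), FTH1, the iron store, from 4085 ± 53.4 to 2556 ± 14.5 CPM. Hypoxia genes fell in 13 of 25 with 2 up (median -0.14, adjusted p = 0.00804) and NF-kB genes in 9 of 24 with 5 up (median -0.08, adjusted p = 0.00385); with an estimated correlation the adjusted p = 0.357 and 0.512.

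Matrix genes rose in 18 of 33 in R158 with 8 down, 20 and 9 adjusted over the list alone (median 0.17, adjusted p = 7.6e-05; adjusted p = 0.155 with an estimated correlation). THBS1, an adhesive matrix protein, rose from 229 ± 9.27 to 472 ± 14.4 CPM. Mesenchymal markers rose in 11 of 20 with 4 down, 11 and 5 adjusted over the list alone (median 0.29, adjusted p = 0.0074; adjusted p = 0.0871 with an estimated correlation), the receptor kinase AXL (also on that arm) by 0.70 ± 0.04. YAP targets rose in 12 of 21, 13 adjusted over the list alone, with 0 down (median 0.23, adjusted p = 0.000431; adjusted p = 0.131 with an estimated correlation). MAPK feedback genes rose in 13 of 28 with 4 down, 14 and 5 adjusted over the list alone (median 0.17, adjusted p = 0.000249; adjusted p = 0.155 with an estimated correlation), AREG, an EGF receptor ligand, by 0.68 ± 0.036. Cholesterol synthesis rose in 16 of 24 with 2 down, 16 and 3 adjusted over the list alone (median 0.19, adjusted p = 0.000675; adjusted p = 0.385 with an estimated correlation). Fatty acid synthesis rose in 9 of 15 with 2 down, 9 and 4 adjusted over the list alone (median 0.13, adjusted p = 0.0186), and TGF-beta targets in 11 of 21 with 4 down (median 0.09, adjusted p = 0.0127); with an estimated correlation the adjusted p = 0.147 for both. Fibroblast markers rose in 3 of 7 with 1 down, 3 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.000249; adjusted p = 0.0681 with an estimated correlation); DCN, a matrix proteoglycan, had 9.07 ± 0.605 CPM in WT and 28.5 ± 1.59 CPM in R158.

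Of 407 genes with at least 2 CPM on chromosome 19 that start from 27 Mb onwards, 94.6% were higher in R158 than in WT (median 0.57) and 90.2% higher than in EV (median 0.62). The 347 genes that start below 25 Mb on the same chromosome had a median of -0.03. The same 407 genes had a median of 0.06 in WT against EV and 0.08 in R149 against WT. Among the largest rises in R158 were those of NLRP9, an inflammasome sensor (chromosome 19, 55708432 to 55738402; 0 to 24.3 ± 1.79 CPM, at least 146-fold), and KIR2DS4, a receptor of natural killer cells (chromosome 19, 54832676 to 54848569; at least 40.3-fold). ZNF568 and ZNF829, which lie side by side on that arm, rose by 3.68 ± 0.355 and 3.64 ± 0.415. Elsewhere POSTN, a matrix protein, rose by 4.54 ± 0.219. The largest falls were of LOC389705, by a ratio of 474 (84.6 to 1.87e+04), LY6D, a keratinocyte surface protein (-4.30 ± 0.157), AUTS2 (-2.92 ± 0.165) and WFDC5 (-2.69 ± 0.304). LOC389705 was low in EV and in R149 as well. The 7SL RNA genes RN7SL2 (-2.73 ± 0.577) and RN7SL1 (-2.50 ± 0.559) were also called, but their WT value rests on WT replicate 1, with 103.61 CPM of RN7SL2 against 15.03 and 11.32 in the other WT libraries.

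**Figure D2:**
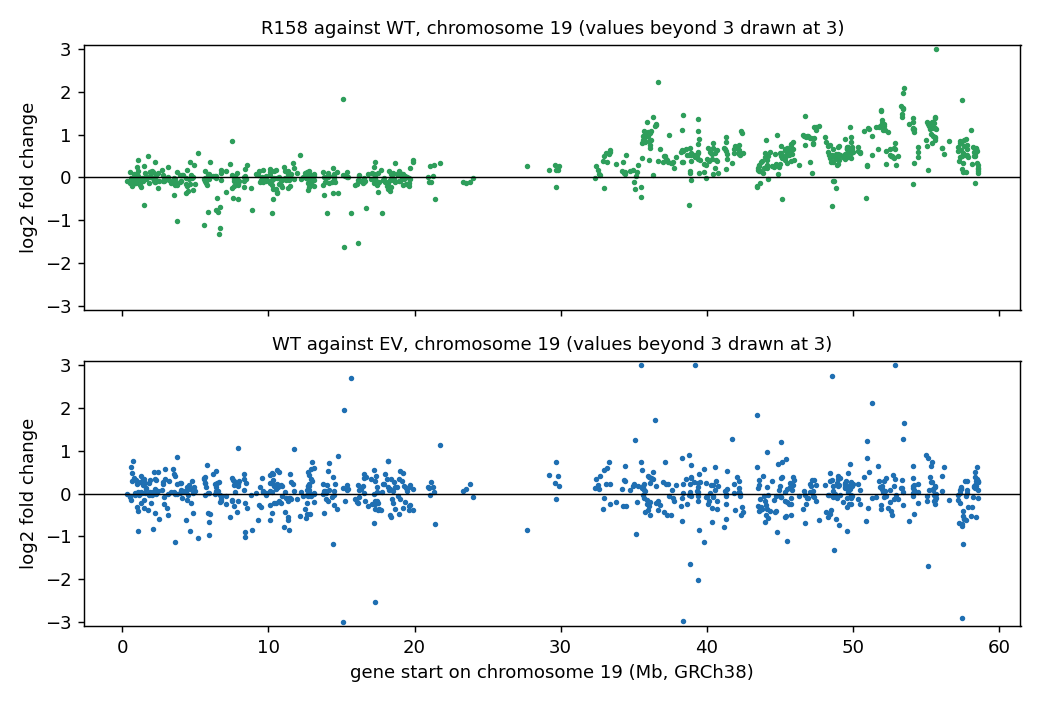
Log2 fold change of each gene against its start on chromosome 19 (Mb) in R158 against WT (top) and WT against EV (below), with points for genes and values beyond 3 drawn at 3. In R158 the 407 genes from 27 Mb onwards had a median of 0.57 and the 347 genes below 25 Mb a median of -0.03.

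R323 against WT addressed the K323R change. Ribosome-making factors and the keratinocyte programme fell in R323, as in R149, and targets of p53 rose. Replication and chaperone genes also fell and the amino acid response rose, but these calls were lost with an estimated correlation (adjusted p = 0.0592, 0.0856 and 0.0594). Of 13622 genes 7595 were called, 3748 higher and 3847 lower, 423 and 314 by at least 2-fold; with WT replicate 1 as the only WT library, assumed to vary like the other groups, 5786 were called.

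Replication genes fell in 36 of 36 in R323 against WT (median -0.79, camera adjusted p = 1.27e-29; adjusted p = 0.0592 with an estimated correlation), FEN1, which trims DNA flaps, from 79.4 ± 1.73 to 33.3 ± 1.22 CPM. Here too the counts adjusted over the list alone were the same except where a second count is given. Genes of G2 and mitosis fell in 28 of 30 with 1 up (median -0.42, adjusted p = 1.12e-11; adjusted p = 0.181 with an estimated correlation), MYBL2 by 1.00 ± 0.063. Targets of p53 rose in 21 of 25 with 3 down (median 0.38, adjusted p = 2.56e-09); MDM2, the ligase that limits p53, rose from 339 ± 9.36 to 540 ± 12.7 CPM and GDF15 by 2.24 ± 0.131. PLK2, a kinase on that list, was not called (adjusted p = 0.915). Nucleolar factors fell in 43 of 47 with 1 up, 44 and 1 adjusted over the list alone (median -0.30, adjusted p = 6.18e-16), LYAR by 1.06 ± 0.047. LYAR lies at the tip of the short arm of chromosome 4, where genes were lower in R323, but it also fell in R149. Nucleotide synthesis fell in 21 of 25 with 1 up (median -0.24, adjusted p = 3.81e-08; adjusted p = 0.101 with an estimated correlation). Chaperones fell in 23 of 24 with 1 up (median -0.38, adjusted p = 1.79e-18; adjusted p = 0.0856 with an estimated correlation), HSP90AA1 from 3902 ± 152 to 1517 ± 52.2 CPM. Mitochondrial ribosomal genes fell in 25 of 33 with 2 up (median -0.26, adjusted p = 3.19e-05) and polyamine genes in 5 of 9 with 1 up, 6 and 1 adjusted over the list alone (median -0.15, adjusted p = 0.0195); with an estimated correlation the adjusted p = 0.191 and 0.149. Ribosomal proteins rose in 32 of 38 (median 0.14, adjusted p = 1.12e-05; adjusted p = 0.331 with an estimated correlation), RPL3 from 2168 ± 73.3 to 2641 ± 12.4 CPM.

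ATF4 targets rose in 18 of 20 in R323 with 1 down (median 1.20, adjusted p = 8.25e-22; adjusted p = 0.0594 with an estimated correlation), CHAC1 from 2.45 ± 0.857 to 34 ± 2.09 CPM. Serine and one-carbon genes rose in 10 of 14 with 2 down (median 0.61, adjusted p = 3.29e-06; adjusted p = 0.101 with an estimated correlation), PHGDH by 1.70 ± 0.129. Fatty acid synthesis rose in 9 of 15 with 4 down (median 0.23, adjusted p = 0.000232), FADS2 by 1.11 ± 0.055. Cholesterol synthesis fell in 16 of 24 with 3 up (median -0.20, adjusted p = 0.000687; adjusted p = 0.314 with an estimated correlation), HMGCS1 by 1.20 ± 0.086. Keratinocyte genes fell in 28 of 29 (median -2.22, or -2.11 with 1 member that had 0 counts in R323 set at its bound; adjusted p = 2.47e-71). PI3 fell from 428 ± 18.9 to 67 ± 5.79 CPM, and SPRR1A, a cornified envelope protein with close copies, by 3.14 ± 0.097. Basal markers fell in 14 of 20 with 4 up (median -0.23, adjusted p = 3.24e-14), KRT17 by 1.84 ± 0.063, and luminal markers in 7 of 14 with 1 up (median -0.22, adjusted p = 0.0232; adjusted p = 0.0937 with an estimated correlation). Matrix genes rose in 20 of 33 with 7 down, 21 and 7 adjusted over the list alone (median 0.33, adjusted p = 6.1e-05; adjusted p = 0.168 with an estimated correlation), and antigen presentation in 8 of 16 with 2 down, 9 and 2 adjusted over the list alone (median 0.23, adjusted p = 0.0153; adjusted p = 0.187 with an estimated correlation). MAPK feedback genes had 11 up and 8 down (median 0.07, adjusted p = 0.0459; adjusted p = 0.421 with an estimated correlation), a call that was lost when some single libraries were left out.

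The largest rises in R323 against WT were of FLRT1 (5.29 ± 0.561), TNFRSF9 (4.80 ± 0.494), PAPPA2 (4.80 ± 0.486), INHBE (4.26 ± 0.323), FPR1, a receptor for bacterial peptides (3.89 ± 0.285), and CHAC1 (3.79 ± 0.176, adjusted p = 6.21e-16). The largest falls were of LOC389705, by a ratio of 394 (70.4 to 1.56e+04), LY6G6C (-4.70 ± 0.45), KRT6C (-4.50 ± 0.138), DSG1 (-4.49 ± 0.25), PDE3B, which breaks down cyclic AMP (-4.26 ± 0.318), and HOPX, a regulator of epithelial differentiation (-4.25 ± 0.361). LOC389705 led the falls in R149 and R158 too and was low in EV, so it was high in the WT line alone. Its fall in each mutant cannot be told apart from a trait of that single line.

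**Figure D3:**
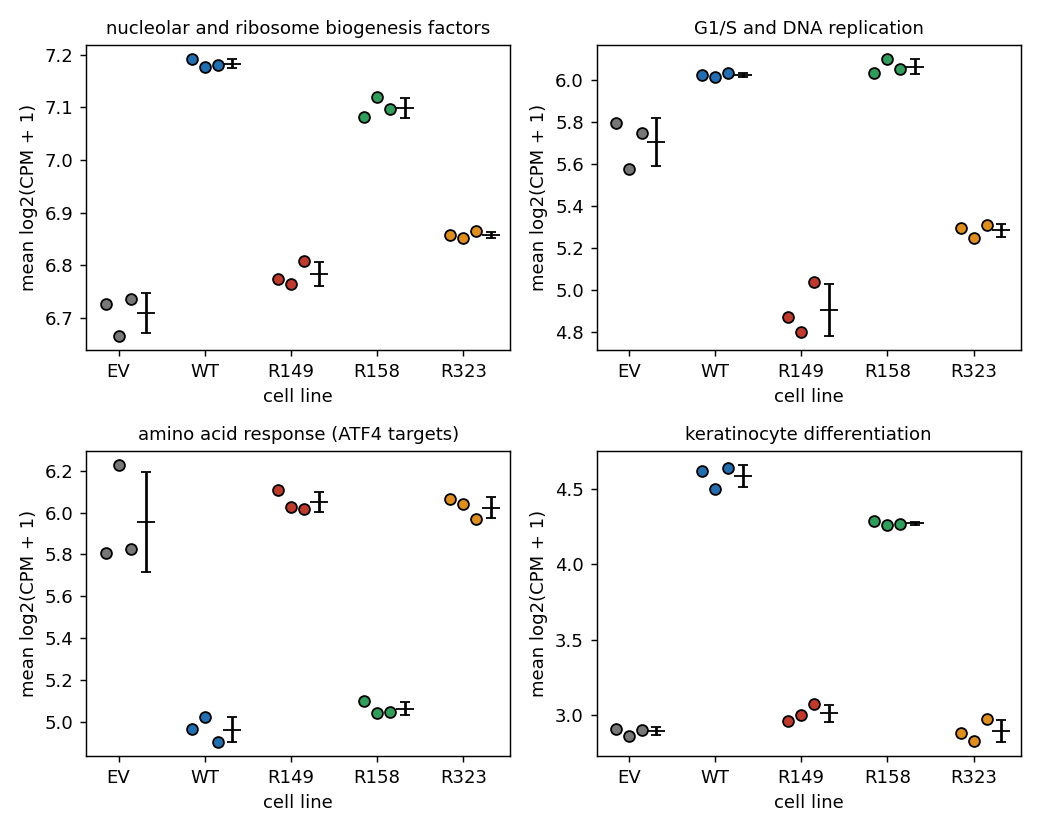
Mean log2(CPM + 1) of the members of the nucleolar, replication (G1/S), ATF4 and keratinocyte lists in each library of the 5 lines, with points for libraries and mean ± SD for groups. Keratinocyte genes were highest in WT, and R149 and R323 lay near EV in the ATF4 and keratinocyte panels and below EV in the G1/S panel.

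In the same direction in all 3 mutants, 681 genes were higher and 745 lower than in WT. Independent lists of those sizes would share 179.3 and 183.2 genes, and in 100 simulated sets with mutants equal to WT at most 1 gene was shared in either direction. All 3 comparisons use the same WT libraries, so part of the excess over independent lists may come from them. The simulated sets held only the spread between replicates of a line, so they do not cover traits of the single WT line. The clearest genes with a shared rise were ITGA10, a collagen receptor (log2 changes of 1.249 in R149, 2.06 in R158 and 1.58 in R323), and RPS6KA2, a kinase below ERK (2.03, 2.19 and 2.60). SULT1E1, which inactivates oestrogen, rose by 3.37, 2.84 and 2.38, and SCNN1G, a sodium channel subunit, by 1.53, 1.07 and 0.97. FADS2 rose by 0.96, 0.72 and 1.11, and MIR205HG, the host of a microRNA of epithelial identity, by 0.65, 0.70 and 0.76. Among the genes lower in all 3, KRT6B changed by -2.95, -2.08 and -3.25, KRT16 by -1.90, -1.80 and -2.19, and KRT6C by -4.79, -1.90 and -4.50. PI3 changed by -3.08, -1.67 and -2.68, the antiprotease SLPI by -1.246, -1.01 and -1.19, and S100A7, an antimicrobial protein, by -2.57, -1.79 and -2.42.

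The mutants were also compared with EV, to ask how much of the WT response each kept. All 3 mutants shared part of it, R158 the most by number of calls. Each of these responses was measured against the same single EV line. A trait of that line would therefore count as kept in every mutant, in the overlaps, shares and correlations below. Of the 8215 genes called in WT against EV, 4374 (53.2%) were called in the same direction in R149 against EV, 6074 (73.9%) in R158 and 4566 (55.6%) in R323. Independent lists would give 2459.6, 2361.8 and 2241; simulated mutants equal to WT gave means of 7557.48, 7579.32 and 7496.91, and simulated unchanged groups at most 1. In direct comparison with WT, 4477 of these genes (54.5%) moved towards EV in R149, 2502 (30.5%) in R158 and 4322 (52.6%) in R323, where simulated mutants equal to WT gave at most 4. Away from EV moved 1238, 628 and 959. The simulated sets held only the spread between replicates of a line. They show neither how far separate lines differ nor how genes picked in the WT line fall back in other lines. Genes that moved towards EV included A2ML1, a protease inhibitor of skin (-2.67 ± 0.059 in R149 and -2.89 ± 0.062 in R323), and in R158 IGFBP7, a growth factor carrier (2.52 ± 0.084), and COL8A1, a short-chain collagen (2.53 ± 0.085). Among the 1146 genes that changed by at least 2-fold in WT, a limit chosen after the data were seen, the median share of the log2 change kept was 0.697 in R149, 0.745 in R158 and 0.677 in R323 (0.986 for simulated mutants equal to WT). Across genes, which are not independent replicates, the changes against EV had covariances with those of WT of 0.4099, 0.4778 and 0.3989, against 0.0172, 0.0171 and 0.0174 for simulated unchanged groups, and Pearson correlations of 0.6835, 0.8223 and 0.7156, against 0.5105, 0.5124 and 0.4983.

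Against EV 8156 genes were called in R149 (4106 higher, 4050 lower), 7830 in R158 (3992 and 3838) and 7433 in R323 (3683 and 3750). The 7SL RNA RN7SL2 had 119.7 to 210.07 CPM in EV, 56.96 to 94.21 in R323 and 5.83 to 9.45 in R149 and R158, so the comparisons of R149 and R158 with EV cannot be separated from that split. In all 3 comparisons ribosomal proteins rose: 38 of 38 in R149 (median 0.40, camera adjusted p = 4.24e-21; adjusted p = 0.0634 with an estimated correlation), 36 of 38 in R158, 37 adjusted over the list alone (median 0.16, adjusted p = 1.64e-11; adjusted p = 0.153 with an estimated correlation), and 38 of 38 in R323 (median 0.39, adjusted p = 2.75e-23; adjusted p = 0.0581 with an estimated correlation). RPL37, on the short arm of chromosome 5 (start 40825262), rose by 0.93 in R149. Bins of that arm below 40 Mb, which do not hold RPL37, were raised against EV in R149. Of the 38 ribosomal protein genes, 7 lie on the long arm of chromosome 19, which was raised in R158. Oxidative phosphorylation rose in 31, 28 and 30 of 31 members (medians 0.40, 0.20 and 0.33; with an estimated correlation adjusted p = 0.052, 0.153 and 0.0495). Matrix genes fell in 19, 21 and 20 of 33, with 9, 7 and 8 up and, adjusted over the list alone, 10 up in R149 (medians -0.36, -0.45 and -0.36; with an estimated correlation adjusted p = 0.0561, 0.0463 and 0.0456). FN1 fell by 2.41, 2.77 and 2.51. YAP targets fell in 17, 15 and 17 of 21, with 18 in R323 adjusted over the list alone (medians -0.57, -0.41 and -0.50; with an estimated correlation adjusted p = 0.0273, 0.0989 and 0.017). Mesenchymal markers fell in 12, 10 and 11 of 20, with 4, 4 and 3 up and, adjusted over the list alone, 5, 4 and 4 up (medians -0.32, -0.34 and -0.30; with an estimated correlation adjusted p = 0.0159, 0.00378 and 0.00342).

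The mutants parted in other lists against EV. Replication genes fell in 33 of 36 in R149 with 0 up, 1 up adjusted over the list alone (median -0.84, adjusted p = 1.35e-16; adjusted p = 0.111 with an estimated correlation). They fell in 29 of 36 in R323 with 1 up (median -0.43, adjusted p = 4.59e-07; adjusted p = 0.299 with an estimated correlation) but rose in 31 of 36 in R158 with 1 down (median 0.39, adjusted p = 3.98e-06; adjusted p = 0.334 with an estimated correlation). CLSPN fell from 46.8 to 11.5 CPM in R149. Nucleolar factors rose in 47 of 47 in R158 (median 0.36, adjusted p = 3.54e-15) and in 27 of 47 in R323 with 3 down (median 0.15, adjusted p = 0.00114; adjusted p = 0.299 with an estimated correlation). In R149 they had 19 up and 6 down (median 0.06, adjusted p = 0.143). ATF4 targets fell in 17 of 20 in R158 with 2 up (median -1.20, adjusted p = 1.24e-09; adjusted p = 0.174 with an estimated correlation), and were not called in R149 (7 up, 5 down, median -0.02, mean 0.125 and an upward test, adjusted p = 0.538) or R323 (6 up, 6 down, median 0.01, adjusted p = 0.542). Keratinocyte genes rose in 24 of 29 in R158 with 2 down (median 1.505, adjusted p = 3.5e-31). They were not called in R149 (12 up, 9 down, median 0.27, adjusted p = 0.0666) or in R323 (11 up, 7 down), where the median was -0.21, or 0 with 1 member at its bound, and the test upward (adjusted p = 0.255). Targets of p53 rose in 15 of 25 in R149 with 5 down, 15 and 6 adjusted over the list alone (median 0.33, adjusted p = 0.000279; adjusted p = 0.052 with an estimated correlation), and in 16 of 25 in R323 with 4 down, 16 and 5 adjusted over the list alone (median 0.43, adjusted p = 1.03e-06). SESN1, a stress sensor for mTORC1, rose by 1.28 in R149 and 1.21 in R323. NF-kB genes fell in 19 of 24 in R158 with 5 up (median -0.70, adjusted p = 1.61e-06; adjusted p = 0.204 with an estimated correlation), IL1B by 1.77. TUB was at least 62.9-fold lower than EV in R149, at least 50.3-fold in R323 and lower by a ratio of 331 (91.2 to 2.74e+03) in R158. AUTS2 was at least 19-fold higher in R149 and at least 30.9-fold in R323, ADD2 had 19.7 ± 1.21 CPM in R149 (230-fold), and PABPC4L was at least 11-fold higher in R323. NLRP9 was at least 120-fold and KIR2DS4 at least 33.1-fold higher in R158. ZNF354C was at least 21.9-fold lower in R149, ADAMTS12 lower by a ratio of 110 (30.1 to 911) in R323 and MAP1B by a ratio of 215 (59.2 to 1.78e+03) in R158. ZNF737 was at least 11.3-fold lower in R149, 11.2-fold in R158 and 9-fold in R323, without a call from DESeq2 (adjusted p = 0.18, 0.185 and 0.211).

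The mutants were compared with each other to ask whether the lines differ. RN7SL2 had 56.96 to 94.21 CPM in R323 and 5.83 to 9.45 in R149 and R158, so the comparisons of R323 with R149 and R158 cannot be separated from the 7SL split. R149 and R323 were the closest pair, with 3015 genes called (1537 higher and 1478 lower in R323), against 8624 for R158 and R149 (4370 and 4254) and 7894 for R323 and R158 (3812 and 4082). Against R149, replication genes in R158 rose in 35 of 36 (median 1.21, camera adjusted p = 1.92e-38) and mitosis genes in 29 of 30 with 1 down (0.90, adjusted p = 2.49e-31). In that pair keratinocyte genes rose in 24 of 29 with 1 down, 25 and 1 adjusted over the list alone (1.51, adjusted p = 1.54e-18), while p53 targets fell in 17 of 25 with 3 up (-0.44, adjusted p = 5.02e-06) and antigen presentation in 13 of 16 with 1 up (-0.51, adjusted p = 1.44e-06). R323 against R158 went the other way: replication genes fell in 36 of 36 (-0.83, adjusted p = 8.51e-26; adjusted p = 0.0876 with an estimated correlation), keratinocyte genes in 26 of 29 with 0 up (-1.39, or -1.35 with 1 member at its bound, adjusted p = 1.34e-29), and p53 targets rose in 18 of 25 with 4 down (0.54, adjusted p = 2.4e-09). ATF4 targets rose there in 18 of 20 with 2 down (1.00, adjusted p = 3.15e-13; adjusted p = 0.127 with an estimated correlation). Between R323 and R149 the cell cycle differed in degree: mitosis genes were higher in R323 in 30 of 30 (0.42, adjusted p = 8.27e-37; adjusted p = 0.0608 with an estimated correlation), replication genes in 30 of 36 with 1 lower (0.41, adjusted p = 2.19e-20) and nucleotide synthesis in 16 of 25, 18 adjusted over the list alone (0.16, adjusted p = 4.05e-09); for the last pair of lists the adjusted p = 0.173 with an estimated correlation. NRF2 targets were lower in R323 in 11 of 23 with 1 higher (-0.15, adjusted p = 2.41e-09; adjusted p = 0.0608 with an estimated correlation).

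Single genes set the mutants apart as well. R158 differed from R149 in KIR2DS4 (at least 33-fold higher), NLRP9 (a ratio of 402, 137 to 1.95e+03) and CRNN, a late epidermal protein (5.17 ± 0.326). It was lower in INHBE (a ratio of 150, 41.2 to 1.25e+03), FLRT1 (102, 27.8 to 847) and the potassium channel KCNT2 (62.1, 16.8 to 519). R323 had more FGF13, a regulator of sodium channels (3.25 ± 0.258), than R149, and more of the 7SL RNAs RN7SL2 (3.26 ± 0.526) and RN7SL1 (2.73 ± 0.5). It had less SLFN13, an RNA-cutting protein (-3.96 ± 0.223), PDE3B (-3.72 ± 0.351) and PLCB1, a phospholipase (-3.40 ± 0.368). Against R158, R323 was higher in INHBE (a ratio of 139, 38.2 to 1.16e+03), FLRT1 (81.1, 22 to 677) and LOC103021296, an uncharacterised locus (4.43 ± 0.524), and lower in NLRP9 (at least 95.5-fold), CRNN (at least 15.5-fold) and ZNF829 (at least 8.23-fold).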

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

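The tests of explanations in this part were chosen after the results they address had been seen, except the one on gene length and GC content, which was written before. The results here stood out because a mutant and WT MYC changed in opposite directions against the same EV libraries while the mutant also differed from WT in the direct test. That held for 1172 genes in R149, 207 in R158 and 722 in R323. In each mutant every gene called in opposite directions was also called against WT, so the direct test removed none and adds no support. The same pattern held for the list of G1/S and DNA replication genes. That list rose in WT against EV and fell in R149 and R323 against EV. Its medians against WT were -1.187 in R149 and -0.789 in R323. With an estimated correlation these list calls against EV were lost (adjusted p = 0.497 in WT, 0.111 in R149 and 0.299 in R323), as was that of R323 against WT (adjusted p = 0.0592).

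R149 and R323 lay apart from WT and R158 in the G1/S, ATF4 and keratinocyte lists, but with an estimated correlation the ATF4 list was not called in R149 or R323 against WT (adjusted p = 0.0875 and 0.0594), in R158 against R149 (adjusted p = 0.166) or in R323 against R158 (adjusted p = 0.127), nor G1/S in R323 against WT and R158 (adjusted p = 0.0592 and 0.0876). The transgene mRNA level is argued against as the whole cause, since R158, which stayed nearer WT, had less mMYC mRNA than R149 (log2 change -0.144, edgeR adjusted p = 0.0017) and than R323, which was higher by 0.449; MYC and mMYC together had 622.3 to 648 CPM in R158, 640.9 to 687.4 in R149 and 755.1 to 779.5 in R323. Gene length and GC content are argued against too, since with their trend removed the smallest of 6 list medians in R149 and R323 was still 0.758 in size. Culture state at harvest cannot be told apart from the mutation, because the labels do not record culture or harvest; EV replicate 2 differed from the other EV libraries by medians of 0.45 in the ATF4 list and -0.181 in the G1/S list, the directions of R149 and R323 against WT, and by -0.063 in the keratinocyte list. The mutation itself, the level of MYC protein and other properties of each line stay open and were not tested, as there was 1 line per mutant.

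A block of genes at the distal long arm of chromosome 19 was raised in R158. Reads shared between zinc finger paralogs are argued against for the 40 other genes of the block from 52702813 to 58599801. Those 40 genes are not named as zinc finger genes, and their median log2 change against WT was 0.961. The 58 zinc finger genes had a median of 0.683, and shared reads among them were not tested. This comparison too was made after the block had been picked for its raised genes. As a hypothesis that stays open, gain of a DNA segment in the line could raise these genes; 97.5% of the 40 other genes were higher in R158, but the block was picked because its genes were raised, so this restates the pattern and does not test it. The genes from 27 to 45 Mb were raised less (median 0.441) than the distal ones, and DNA was not measured.

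The level of 7SL RNA split the WT libraries and followed the other groups. RN7SL1 had 49.97 to 114.4 CPM in EV, 55.82 in WT replicate 1, 10.38 and 7.35 in the other WT libraries, at most 7.03 in R149 and R158, and 32.84 to 46.77 in R323, while RN7SK went the other way (0.78 CPM in WT replicate 1 and 4.44 and 3.97 in the others). Whether a library batch is the source of WT against EV or of R323 against WT stays open, because 1 library bears on it: the log2 changes from WT replicate 1 alone had median ratios of 0.985 and 0.972 to those from the other WT libraries, and both sides share the EV or R323 libraries. For R149 and R158 against EV, and for R323 against R149 and R158, the split runs with the groups, so a batch could not be separated from them there. No biological explanation of the 7SL level was tested.

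With 3 libraries per group there are only 10 ways to split a pair of groups, too few for a share under 0.05. In each of the 10 comparisons 1 of 10 splits, the real one, called as many genes with edgeR, and the highest other split called 0. Other splits held 297 to 704 genes with an unadjusted edgeR p below 0.05 in WT against EV and 311 to 1068 in R149 against EV. Such splits put part of the group difference into the spread within a side, so few calls follow from the split itself. For the F-test over the 5 groups, 1 of 100 splits reached 11711 genes and the highest other reached 2305. This argues against chance only in how the libraries fall into lines. It does not bear on which line was picked, as there was 1 line per construct. The number of lists called set the real split less apart, as the camera test at its preset correlation also called many lists in other splits. Each other split of a pair kept part of the group difference, since its sides held unequal numbers of libraries from each group. The list counts of those splits therefore do not measure false calls. In WT against EV 5 of 10 splits called at least as many lists (real 17, highest other 19), and in R158 against EV 2 of 10 did (25 and 25). In the other comparisons 1 of 10 did: R149 against WT 22 (highest other 18), R158 against WT 18 (14), R323 against WT 19 (16), R149 against EV 17 (15), R323 against EV 21 (17), R158 against R149 24 (21), R323 against R149 18 (12) and R323 against R158 24 (17).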

How the results depend on the processing

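The alternatives were fixed beforehand except the pair named as added, which was chosen after the data were seen. All 176 alternative counts of genes called stayed within 1.5 times the reported count, with ranges of 6572 to 8362 in WT against EV, 6804 to 8505 in R149 against WT, 2837 to 4355 in R158 against WT and 5786 to 7688 in R323 against WT. The counts of lists called moved with the test. With a correlation estimated for each list, 6 lists were called in WT against EV, 8 in R149 against WT, 0 in R158 against WT, 5 in R323 against WT, 2 in R149 against EV, 6 in R158 against EV, 6 in R323 against EV, 7 in R158 against R149, 0 in R323 against R149 and 3 in R323 against R158. With fry, 34 lists were called in WT against EV, 35 in R149 against WT, 33 in R323 against WT, 29 in R149 against EV and 32 in R323 against EV. The cause was not tested. The log2 fold change of MYC, WT against EV, kept its direction and call throughout (-1.446 to -1.396). For the named genes, counted over all settings and comparisons, 17656 values kept their direction and call, 99 lost the call (15 of them with DESeq2 and 22 with WT replicate 1 as the only WT library), 195 gained it and 1 reversed: LCP1, R323 against WT, was at 0.142 with WT replicate 1 as the only WT library, an added setting. The replicate block gave 8195, 8444, 4204 and 7594 genes in WT against EV and in R149, R158 and R323 against WT. Libraries with the same number showed no common deviation (median correlation 0.005, 1 of 30 above 0.1). The pair above 0.1 was WT replicate 1 with R158 replicate 1 (0.148), both among the libraries that stood apart. These values cannot show whether libraries with the same number were grown or prepared together. Without 3 libraries that stood apart, the other added setting, the gene counts of the same comparisons were 7317, 8395, 3763 and 7441. Depth limits genes with few counts: those with 0 counts in a group have only a bound.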

Other observations

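The regions below were chosen after a scan of 150 bins per comparison, so after their values were seen, and no explanation of them was tested. At the tip of the short arm of chromosome 4 (53285 to 5814305), 48 genes had a median log2 change in R323 of -0.51 against WT, -0.399 against EV, -0.433 against R149 and -0.422 against R158, and of 0.034 in WT against EV. On the short arm of chromosome 5, genes that start below 20 Mb and from 20 to 40 Mb had medians against EV of 0.339 and 0.329 in WT, 0.457 and 0.473 in R149, and 0.234 and 0.222 in R323, and of -0.212 and -0.235 in R158 against WT. SDHA, of the respiratory chain, lies on that arm, and it rose by 0.469 in WT against EV. Genes on the long arm of chromosome 4 from 160 to 180 Mb had a median of -0.2 in R323 against EV, and those on chromosome 3 from 140 to 160 Mb had -0.202 in R149 against WT.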
